A study of Homo sapiens with 4 samples.

How the data were processed

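The binding of BAF45D to DNA was measured by CUT&Tag in H9 human embryonic stem cells (ESC) and in spinal cord neural stem cells (NSC) derived from them, with 2 libraries of each cell type. BAF45D is the product of the gene DPF2 and a subunit of the BAF chromatin remodelling complex. In CUT&Tag an antibody directs a transposase to the DNA next to its target, so that sequenced fragments come from the neighbourhood of the bound protein. Per the labels' protocols, each assay used 100000 cells, and the NSC were obtained by 10 days of neural induction followed by culture in maintenance medium. The labels number the libraries ESC1, ESC2, NSC1 and NSC2 and do not say whether they came from separate cultures, so differences between libraries of a cell type may be technical in origin.

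Reads were handled with FastQC, Trimmomatic and BWA 0.7.12 on hg38, per the submitters' processing notes. Peaks were called separately for each library with MACS2 2.1.0.20150420, per the file headers, without a control library, at a q threshold of 0.05, with a shift of -100 bp, an extension of 200 bp, all duplicates of the input kept, and a regional background of 10000 bp. The input was named as unique and deduplicated reads, and the effective genome size was 3099750718 bp, per the file headers. For each peak the authors deposited the pileup at the summit as a signal value, computed from that library alone. The deposited −log10 p and −log10 q values describe the peak against the local background of the same library. The fold enrichment is the authors' ratio of the pileup to that background, also within 1 library. These strengths were therefore used only to describe, rank or filter peaks within 1 list, and libraries were compared by the presence or absence of peaks. No library with an untargeted antibody was analysed here, so a peak was not measured against the background of the assay.

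The file headers gave 20734829 tags for ESC1, 18953543 for ESC2, 5566407 for NSC1 and 5377831 for NSC2. A peak list has no read counts for places without a peak, so the absence of a peak means that the signal did not pass the threshold in that library, and no lower limit of binding was derived. Entries of the lists that shared the same start and end (several summits in 1 interval) were joined, with the strongest −log10 q kept. The main results used chromosomes 1 to 22 and X.

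Gene positions came from a RefSeq gene table of GRCh38.p14 with a start and an end for each gene, which is the build family of the peaks. Strand, transcripts, exons and the genome sequence were not used here. A planned promoter definition was therefore replaced by the window within 1 kb of either end of a protein-coding gene, called the gene-end window below, and peaks were placed at gene ends, inside genes or outside genes. A peak in a gene-end window may lie at the 3′ end of a gene, or at the promoter of a neighbour. The planned motif and GC content results were not run, because they need the genome sequence.

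Peaks of 2 libraries were called shared when they overlapped by at least 1 bp, and overlaps were given as a percent of the shorter list. Chance was taken from 100 random placements of the peaks on the same chromosomes. For regions, overlapping peaks of the 4 libraries were merged. Regions and genes were then classed as NSC-only (a peak in both NSC libraries and in no ESC library), ESC-only (the converse), or shared by all 4 libraries. With 2 libraries against 2, an exact permutation test cannot give a two-sided p below 0.333, so that test could not pass a threshold of 0.05 for any single value, and values per library are given with their spread. Intervals of shares are 95% Wilson intervals and cover counting error only.

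A set of 33 gene lists was tested in 2 ways. At gene ends, the share of a list in each of the 3 classes was compared with all other genes among 19974 protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 99 tests. By locus, a gene was counted when a peak lay in the gene or within 10 kb of it in both NSC libraries and in no ESC library, and the count was placed among 10000 random lists matched on deciles of gene length (a permutation of gene labels within deciles), with adjustment over 33 lists. Genes are not replicates, and both tests describe these 4 libraries. For the 4 HOX clusters with 10 kb on either side, peak numbers were compared with 10000 windows of the same length centred on random gene ends, a randomisation test that is not exact. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, except that the gene-end window was set once the gene table had been seen, and that alternatives named as chosen later were added. That rule took the 10 genes of each class with the highest mean rank of −log10 q within the lists, up to 4 members per class of each list described, a fixed set of markers with DPF2 and the HOX genes, and the 5 strongest regions of each class. Some genes that the rule takes are not reported here.

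The alternatives were lists shortened to the length of the shortest, a −log10 q of at least 5, all sequences of the files, each library left out, an overlap of 50% of the shorter peak or 200 bp around summits, a gene-end window of 2.5 kb, loci of 50 kb and HOX clusters without flanks. The interval and list routines were tested on simulated data. Interval counts equalled a direct count for 200 of 200 genes. In a simulation over the same 19974 genes, of 200 given planted NSC peaks among random peaks, 192 were classed as NSC-only, the other 8 met a random ESC peak, and 55 genes without planted peaks were classed as NSC-only from random peaks. A list planted at 3 times the share of the other genes was found in 100% of 100 simulations by both tests, and unplanted lists passed an unadjusted 0.05 in 3.2% (gene ends) and 1.8% (locus). These simulations drew each gene independently. Their rates therefore do not cover lists whose genes share peaks, such as HOX genes and clustered protocadherins. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.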

Results

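BAF45D occupancy was profiled in 2 ESC libraries and 2 NSC libraries to compare where this BAF complex subunit sits on the genome before and after H9 embryonic stem cells became spinal cord neural stem cells. H9 is an established human embryonic stem cell line. The files held 1 peak list per library, with 4204 peaks in ESC1, 12533 in ESC2, 29783 in NSC1 and 24669 in NSC2 on chromosomes 1 to 22 and X. Peak strengths are the authors' own −log10 q values within each list.

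The NSC libraries had more BAF45D peaks than the ESC libraries, from fewer reads. The mean was 27226 ± 3616 peaks in NSC and 8368.5 ± 5889 in ESC (SD, n = 2 each), a ratio of 3.25. The lower NSC library still had 1.97 times the peaks of the higher ESC library. Tags went the other way, with 5566407 and 5377831 in NSC1 and NSC2 and 20734829 and 18953543 in ESC1 and ESC2, a ratio of the means of 0.276. Peaks covered 11.8 and 9.17 Mb in NSC1 and NSC2, against 1.32 and 4.13 Mb in ESC1 and ESC2. Within each list, the median fold enrichment was 5.48 and 5.49 in NSC1 and NSC2 and 4.58 and 4.62 in ESC1 and ESC2. Folds of separate lists share no scale, and the lowest pileup was 4 in both NSC lists and 8 and 7 in ESC1 and ESC2. In peak number, the ESC libraries differed from each other by a factor of 2.98, and the ratio of the means was 2.17 without ESC1 and 6.48 without ESC2. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333.

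**Figure D1:**
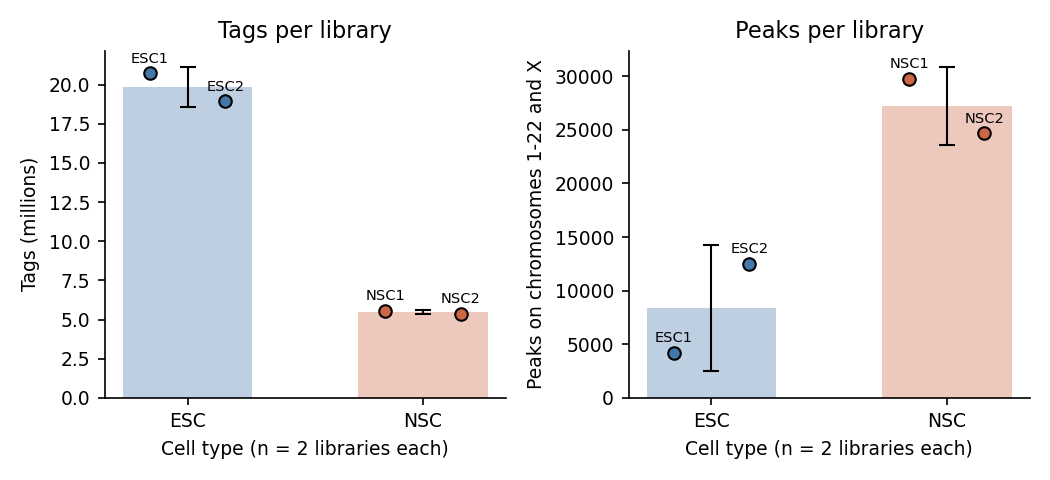
Tags (left) and peaks on chromosomes 1 to 22 and X (right) per library, for ESC (blue) and NSC (orange). Points are libraries, bars are means and error bars are SD (n = 2 each). The NSC libraries lie lowest for tags, at 5566407 and 5377831, and highest for peaks, at 29783 and 24669.

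As a percent of the shorter list, libraries of the same cell type shared more peaks than libraries of different cell types. The NSC libraries shared 18389 peaks, 74.5% of the shorter list (95% Wilson interval 74.0 to 75.1), and the ESC libraries shared 2490 peaks, 59.2% (57.7 to 60.7). The 4 pairs of an ESC and an NSC library shared 36.4% to 39.2%. In number, ESC2 shared 4833 and 4562 peaks with NSC1 and NSC2, more than with ESC1, and ESC1 shared 1633 and 1650. The highest of 100 random placements gave 0.999% or less for each pair. The ESC pair stood at 46.2% and the NSC pair at 70.0% at equal list length.

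In both cell types, BAF45D peaks lay at gene ends far more often than random positions did. The share of peaks within 1 kb of a gene end was 29.0% ± 3.96 in ESC and 28.4% ± 0.833 in NSC (SD, n = 2 each), against 3.19% and 2.98% for random positions, and the cell types differed by less than the spread between the ESC libraries. The share inside genes but away from their ends was 35.4% ± 0.626 in NSC and 28.9% ± 1.36 in ESC. The share outside genes was 36.2% ± 0.207 and 42.0% ± 5.32.

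Merging the lists gave 44534 regions, of which 13646 were NSC-only, 736 were ESC-only and 1458 were shared by all 4 libraries. Shared regions lay mostly at gene ends (62.1%, 95% Wilson interval 59.6 to 64.5), NSC-only regions much less often (21.8%, 21.1 to 22.5) and ESC-only regions rarely (9.10%, 7.23 to 11.4). The strongest NSC-only regions on hg38 were in SMIM19 (chromosome 8, 42543001 to 42543584, −log10 q 63.0 and 52.9 in NSC1 and NSC2) and in EPS8, an actin regulator (chromosome 12, 15629102 to 15629518, 59.8 and 53.2). Others were 735 bp from FIGN, which encodes the microtubule-severing protein fidgetin (chromosome 2, 163601006 to 163601876), and 150 kb from ADCY2, an adenylyl cyclase gene (chromosome 5, 7244768 to 7245718). The fifth lay in ANKRD18DP (chromosome 3, 198071773 to 198072257). Among the 5 strongest ESC-only regions, 4 overlapped no annotated gene (chromosome 6 at 58784710, chromosome 4 at 49103452 and 49135949, and chromosome 16 at 34586709), and 1 lay in SLC38A8, an amino acid transporter gene (chromosome 16, 84013896 to 84014703, 24.4 and 96.8 in ESC1 and ESC2). The strongest region shared by all 4 libraries overlapped MTATP6P1, a nuclear copy of mitochondrial sequence, and LOC102724250 (chromosome 1, 633798 to 634251). The other 4 lay on chromosome 4 at 49149237, chromosome 3 at 93470259, chromosome 17 at 22521267, which is 558 bp from the mitochondrial pseudogene MTCYBP13, and in the immunoglobulin kappa locus on chromosome 2 at 89833160. Background calls were not filtered or measured, so the strongest regions of these classes are not shown to be sites of BAF45D. Without ESC1, the shorter list, there were 7272 ESC-only and 4113 shared regions, without ESC2 there were 2401 ESC-only regions, and without NSC2 there were 24945 NSC-only regions. At equal list length 1696 regions were NSC-only and 790 shared, and at −log10 q of at least 5 the 3 classes held 7364, 296 and 766.

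Regions bound in both NSC libraries were found again in ESC mainly at gene ends. Of 5806 such regions at gene ends, 48.8% had a peak in at least 1 ESC library (95% Wilson interval 47.5 to 50.1), against 1313 of 11987 regions elsewhere (95% Wilson interval 10.4% to 11.5%). The gap held at each of the 10 levels of strength within the NSC lists. In the strongest decile, 90.3% (88.0 to 92.1) of the gene-end regions and 27.7% (25.0 to 30.6) of the others had an ESC peak. This comparison was chosen after the data were seen.

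**Figure D2:**
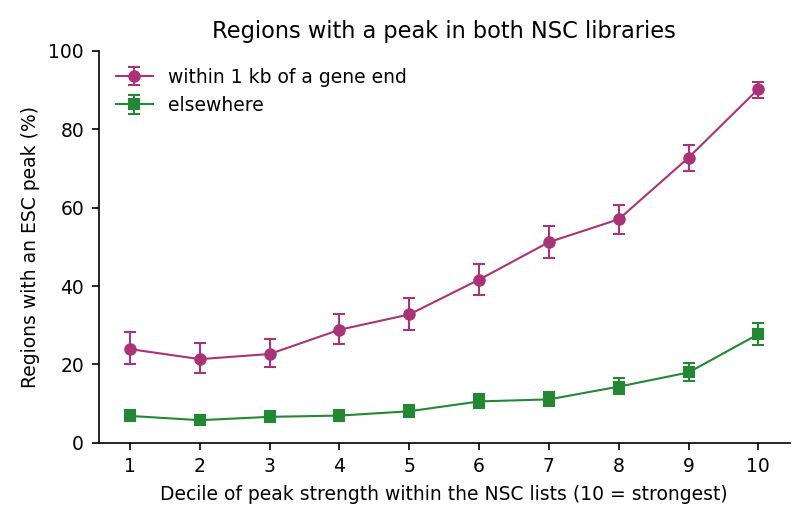
Percent of regions with a peak in both NSC libraries that also had a peak in at least 1 ESC library, by decile of peak strength within the NSC lists (1 weakest, 10 strongest), with 95% Wilson intervals. Circles are regions within 1 kb of a protein-coding gene end and squares are all others. At the strongest decile the shares are 90.3% and 27.7%.

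At the level of genes, BAF45D was called at the ends of 8557 and 7602 of 19974 protein-coding genes in NSC1 and NSC2, and of 1332 and 4553 in ESC1 and ESC2. The NSC-only class held 3230 genes, the ESC-only class 49 and the class shared by all 4 libraries 1174. DPF2 itself, on chromosome 11 at 65333852 to 65354262, was NSC-only, with −log10 q of 7.14 and 6.61. Strongest in the NSC-only class were TMEM88, which encodes a membrane protein that inhibits WNT signalling (80.4 and 96.9 in NSC1 and NSC2), FIGN (51.2 and 56.3), WDR88 (42.3 and 42.4), GGPS1 of isoprenoid synthesis (40.9 and 35.1) and PARG, which removes poly(ADP-ribose) (41.9 and 33.6). The next were DIABLO, a mitochondrial promoter of apoptosis, the homeobox gene IRX5, CDCA3, the autophagy gene ATG10, and FIBP. At TMEM88, WDR88, GGPS1, IRX5 and CDCA3, both ESC libraries had a peak within 10 kb of the gene but outside the gene-end windows. At TMEM88 the NSC peaks were stronger than in any NSC-only region, so the merged region there also held an ESC peak. A gene called NSC-only may thus share its site with ESC.

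In the ESC-only class, the strongest genes were TAF11L5 (17.8 and 15.9 in ESC1 and ESC2), FBXO27 (9.39 and 28.1), PTER (10.6 and 15.4), ESRP1, a splicing regulator of epithelial cells (8.91 and 17.8), and the clock gene PER1 (11.1 and 13.3). They were followed by ZFP36L1, which promotes mRNA decay, GAGE2A, CFD, SAXO5 and TAF11L10. At PER1 and SAXO5, both NSC libraries had a peak within 10 kb but outside the gene-end windows. TAF11L5, TAF11L10 and GAGE2A belong to families of near-identical copies, where reads may be shared. Among the genes shared by all 4 libraries with the highest ranks were NDUFA11 and its neighbour VMAC, RBM39, FAM72B and its neighbour SRGAP2C, AGBL5, PGBD2, PHF12 and HDGFL2. NDUFA11 and VMAC had the same peak at their ends, as did FAM72B and SRGAP2C, which belong to duplicated families. At equal list length the NSC-only, ESC-only and shared classes held 440, 251 and 739 genes, and at −log10 q of at least 5 the last 2 held 25 and 592. Without ESC1 they held 473 and 3656, without ESC2 there were 5712 NSC-only and 84 ESC-only genes, and without NSC1 81 were ESC-only.

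Several marker genes of the neural state were NSC-only. Of 31 pluripotency genes, 3 and 6 were called at their ends in ESC1 and ESC2, where 6.67% and 22.8% of all genes were called, and 5 and 4 in NSC1 and NSC2, where 42.8% and 38.1% were. NES, the neural stem cell intermediate filament (7.41 and 3.01 in NSC1 and NSC2), SOX1 (5.01 and 2.93), MEIS1 (7.42 and 8.65), MEIS2 (10.3 and 8.01), ZIC1 (32.8 and 16.8), and the ventral spinal cord factors NKX6-1 (8.66 and 10.0) and OLIG2 (4.45 and 7.36) were NSC-only. At SOX1, both ESC libraries had a peak within 10 kb but outside the gene-end windows. ESC2 had 2, 3 and 1 such peaks at NES, MEIS1 and ZIC1. SOX2 was bound in all 4 libraries (3.49 and 18.0 in ESC, 16.3 and 7.66 in NSC), as were LIN28A (7.96, 16.4, 11.4 and 5.19) and IRX3 (3.70, 16.6, 13.3 and 11.3). No library had a peak at the ends of POU5F1, NANOG, LIN28B, PAX6, CDX2 or OTX2, and DNMT3B had one in ESC2 alone (1.94). Within 10 kb of POU5F1, each of the 4 libraries had 1 peak, and none had one at NANOG.

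Regulators of neural progenitors were over-represented among NSC-only genes. Of 31 members, 12 were NSC-only (38.7% against 16.1% of other genes, odds ratio 3.28, Fisher's exact test, adjusted p = 0.0355). They included POU3F2, ZIC1, ZIC2 (18.1 and 17.5 in NSC1 and NSC2) and VIM, which encodes vimentin (21.0 and 10.4). Members with a gene-end peak numbered 16 and 16 in NSC1 and NSC2, and 2 and 4 in ESC1 and ESC2. Ribosomal protein genes were also over-represented, with 26 of 83 NSC-only (odds ratio 2.38, adjusted exact p = 0.0125), among them RPS28 (22.9 and 18.7), RPS2 (25.2 and 14.3), RPL9 and RPLP2. Their ends were called at 73 and 70 members in NSC1 and NSC2, and at 12 and 41 in ESC1 and ESC2. Across all genes, 42.8% and 38.1% were called in NSC1 and NSC2, and 6.67% and 22.8% in ESC1 and ESC2. Of their 73 gene-end regions with a peak in both NSC libraries, 40 had an ESC peak, against 34.8 at the same NSC strength (adjusted permutation p = 0.772). The call thus does not show binding particular to NSC. The neural call was lost without ESC2 (odds ratio 1.81, adjusted exact p = 0.462), without NSC1 (2.68, 0.111), without NSC2 (2.44, 0.131), at −log10 q of at least 5 (2.86, 0.218) and, with the ribosomal call, at equal list length (6.63, 0.113, and 4.14, 0.078). Without ESC2 the ribosomal odds ratio was 4.68 (adjusted exact p = 3.05e-10).

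Below the threshold, the closest lists were HOX genes of paralog groups 1 to 5 and WNT genes. The full HOX list had 9 of 39 members NSC-only (odds ratio 1.56, Fisher's exact test, adjusted p = 0.856), and groups 6 to 9 had 2 of 12 (1.04). HOX genes of paralog groups 1 to 5 had 7 of 15 members NSC-only (odds ratio 4.54, Fisher's exact test, adjusted p = 0.061) and WNT signalling 14 of 42 (2.60, adjusted p = 0.061), including ZNRF3 (13.4 and 10.9), TCF7L1 (13.5 and 10.0), AXIN1 and FZD5. Both passed without ESC1 (adjusted exact p = 0.0343 each), and at equal list length no WNT gene was NSC-only. The HOX 1 to 5 odds ratio was 2.19 without ESC2 (adjusted exact p = 0.533), 2.05 at −log10 q of at least 5 (1) and 6.86 at equal list length (0.379), and among its 7 genes HOXB3 and HOXB5 had the same peak, as did HOXC4 and HOXC5. Subunits of the BAF complex had 10 of 31 members NSC-only (2.47, adjusted exact p = 0.243), including SMARCB1 (16.0 and 7.15), PBRM1 and SMARCA2, and 4 in all libraries, namely ARID2, ACTL6A, SS18 and SMARCC2. This list passed with windows of 2.5 kb (3.52, adjusted exact p = 0.0197). Spinal cord domain factors had 3 of 41 (0.409, adjusted exact p = 0.604), namely IRX5, NKX6-1 and OLIG2. Pluripotency genes had 2 of 31, among them KLF4 (0.357, adjusted exact p = 0.797). Markers of other cell types did not pass: 2 of 25 neuronal, 1 of 18 glial, 3 of 16 neural crest, 1 of 28 mesoderm and endoderm, 4 of 18 fibroblast, 0 of 22 blood and 0 of 20 liver and gut genes were NSC-only. Without ESC2, under-representation passed for pluripotency genes (odds ratio 0.172, adjusted exact p = 0.0443), spinal cord domain factors (0.197, 0.0209), axial progenitors (0, 0.0209), mesoderm and endoderm (0.0923, 0.0209), blood (0, 0.0209) and liver and gut (0, 0.0242).

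Olfactory receptor genes, whose main site of expression is the nose, were under-represented among NSC-only genes (6 of 392, odds ratio 0.0789, Fisher's exact test, adjusted p = 3.08e-20) and among genes of all 4 libraries (0 of 392, adjusted p = 3.17e-09). Replication-dependent histone genes (1 of 69, 0.0759, adjusted exact p = 0.00377) and clustered protocadherins (1 of 53, 0.0994, adjusted p = 0.0355) were also under-represented in the NSC-only class. Histone gene ends were called at 42 genes in ESC2, 39 in NSC1, 34 in NSC2 and 6 in ESC1. Protocadherin gene ends were called at 23 genes in ESC2, NSC1 and NSC2 each, and at 1 in ESC1. These genes shared peaks, since only 2 distinct gene-end regions of the list had a peak in both NSC libraries. Of these 2 regions, 0 had an ESC peak, so both were NSC-only as regions. The shortfall of protocadherin genes is thus not seen in gene-end regions, though 2 are too few to decide. Fisher's exact test counts such genes as separate, so the protocadherin p-values overstate the evidence. Copies within both families are alike in sequence, so reads may be shared between members. Without ESC2 the odds ratios of these 2 families turned to 1.71 and 1.92 (adjusted exact p = 0.178 and 0.142), and that of olfactory receptors was 0.0378. Without NSC2 those of olfactory receptors, histone genes and protocadherins were 0.0512, 0.207 and 0.0646. These calls were also lost at −log10 q of at least 5, with odds ratios of 0.780 for histone genes and 0 for protocadherins (adjusted exact p = 1 and 0.0685), and at equal list length, with 0, 0 and, for olfactory receptors, 0.224 (adjusted exact p = 1, 1 and 0.153).

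Genes bound in all 4 libraries were enriched for ribosomal protein genes (12 of 83, odds ratio 2.72, Fisher's exact test, adjusted p = 0.046), such as RPS19. This call was lost without NSC1 (2.69, adjusted exact p = 0.0587), without NSC2 (2.65, 0.0562) and under 4 other settings. Without ESC1 the odds ratio was 4.19 (adjusted exact p = 1.65e-08), and histone genes (4.12, 5.09e-07) and protocadherins (3.18, 0.00187) passed too, while HOX (0, 0.0075), spinal cord domain (0.111, 0.0309), forebrain and midbrain (0, 0.0474) and mesoderm and endoderm genes (0, 0.0343) were under-represented. Protocadherin genes shared a few peaks, so their Fisher's exact test counted the same peaks many times. In the ESC-only class, with 49 genes, 0 of the 33 lists passed, and 0 did so at an unadjusted p under 0.05. Its members from the pluripotency and axial progenitor lists were L1TD1, an RNA-binding protein of pluripotent cells (3.29 and 4.52 in ESC1 and ESC2), and SP8 (5.26 and 8.57), near which both NSC libraries also had 1 peak within 10 kb. The axial list passed with windows of 2.5 kb (odds ratio 30.6, adjusted exact p = 0.0303). Without ESC1, 4 lists were over-represented in this class, namely pluripotency genes (odds ratio 6.15, adjusted exact p = 0.0343), FGF and EGF signalling (5.36, 0.0474), histone genes (4.71, 0.012) and zinc finger ZNF genes (2.19, 0.0075).

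When genes with a peak in the gene or within 10 kb were counted, HOX genes had the highest ratios to random lists. Of 39 HOX genes, 17 had a peak in both NSC libraries and none in ESC, against 5.74 in random lists matched on deciles of gene length (adjusted permutation p = 0.00165). The excess lay in paralog groups 1 to 5, with 11 of 15 against 2.23 (adjusted permutation p = 0.00165), and 6 to 9, with 6 of 12 against 1.64 (adjusted p = 0.0247), while groups 10 to 13, which pattern the hindmost body, had 0 of 12 against 1.87 (adjusted p = 0.492). HOX genes lie side by side and shared regions. The random lists treat genes as separate, so these permutation p-values of HOX genes overstate the evidence. Random lists are scattered over the genome, whereas HOX genes fill 4 clusters with overlapping flanks. A count of distinct regions is therefore low in advance for HOX genes, so a call lost by it does not show that no excess exists. In windows of the clusters' own length, not matched on the number of gene ends, 12 NSC-only regions stood against 3.66, as given below. Counting distinct regions in place of genes, an alternative chosen after the data were seen, ended the call for all HOX genes (ratio 1.08, adjusted permutation p = 0.911) and groups 6 to 9 (1.70, 0.454), and groups 1 to 5 still passed (2.61, 0.042), but not as distinct regions without ESC2 (1.67, 0.292). Counted as genes without ESC2, the calls for all HOX genes (1.44, adjusted permutation p = 0.216) and groups 6 to 9 (1.78, 0.316) were lost. TGF-beta, BMP and nodal signalling genes followed with 16 of 37 against 7.61 (adjusted permutation p = 0.0132), among them ACVR1, SMAD4 and TGFB3. WNT signalling (15 of 42 against 8.66, adjusted permutation p = 0.104), BAF subunits (12 of 31 against 6.90, 0.156) and neural progenitor genes (9 of 31 against 5.54, 0.325) did not pass, although WNT genes (ratio 1.95, 0.0396), Hippo and AP-1 genes (2.77, 0.00264) and ribosomal protein genes (2.26, 0.0022) did at −log10 q of at least 5. Hippo and AP-1 (7.61, adjusted permutation p = 0.0022) and Hedgehog signalling genes (4.86, 0.0396) passed at equal list length. The ratio of HOX groups 1 to 5 was 2.41 without ESC2, where it still passed (adjusted permutation p = 0.0033). Without ESC2, neural progenitor (1.71, adjusted permutation p = 0.017), Hippo and AP-1 (1.69, 0.0313) and ribosomal protein genes (2.05, 0.0022) passed, and liver and gut genes were fewer than in random lists (0.133, 0.011), as without NSC2 (0, 0.033).

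Clustered protocadherins (0 of 53 against 11.5, adjusted permutation p = 0.00165), olfactory receptors (10 of 392 against 55.3, 0.00165), histone genes (1 of 69 against 8.29, 0.0132) and zinc finger ZNF genes (74 of 510 against 102, 0.0132) had fewer such genes than random lists. Protocadherin genes lie in clusters and shared regions, so the 53 genes are not separate loci. Distinct regions are also fewer in advance for clustered genes, since random lists are scattered over the genome. As distinct regions, histone genes did not pass (0.429, adjusted permutation p = 0.0706) except without NSC1 (0.395, 0.0132), and ZNF genes did not without ESC2 (0.882, 0.0989). Without ESC2, the call for protocadherins was lost (0.780, adjusted permutation p = 0.271), histone genes turned to 2.15 (0.0022) and ZNF genes to 1.00 (0.995), and olfactory receptors stood at 0.0967. Histone genes stood at 0.190 without NSC1. ZNF genes also fell short without NSC1 (0.829, 0.11) and without NSC2 (0.829, 0.0709), as did TGF-beta genes without NSC2 (1.64, 0.13), at equal list length (2.87, 0.207), at −log10 q of at least 5 (1.76, 0.162) and within 50 kb (1.67, 0.279). At equal list length, HOX groups 6 to 9 (7.19, adjusted permutation p = 0.207), protocadherins (0, 0.207), olfactory receptors (0.291, 0.0682), histone genes (0, 0.9) and ZNF genes (0.998, 1) did not pass. At −log10 q of at least 5, groups 6 to 9 (2.33, adjusted permutation p = 0.584), histone genes (0.632, 0.764) and ZNF genes (0.899, 0.655) did not pass, and protocadherins stood at 1.04.

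**Figure D3:**
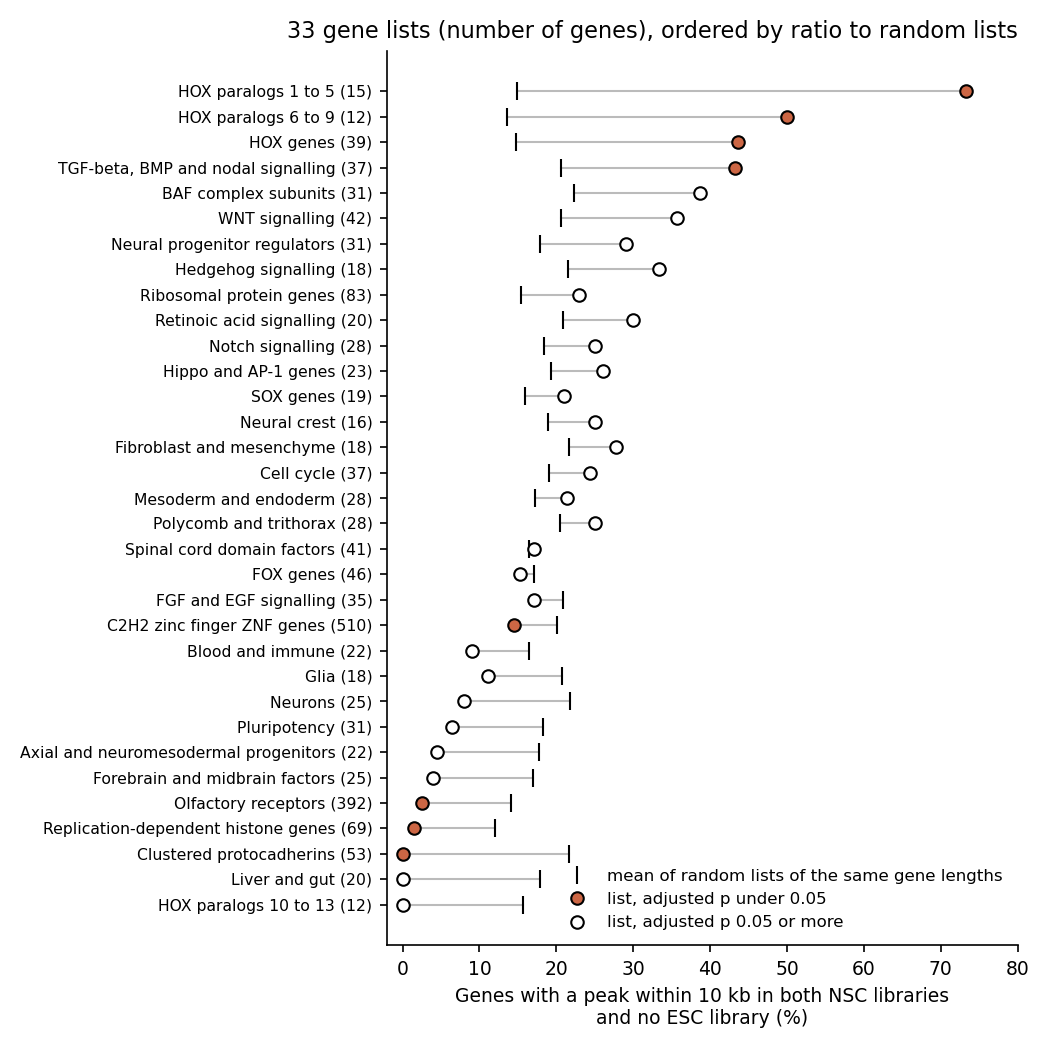
Percent of genes of each of the 33 lists (number of genes in brackets) with a peak within 10 kb in both NSC libraries and in no ESC library. Circles are the lists, filled where the adjusted p is under 0.05, and ticks are means of 10000 random lists matched on deciles of gene length. HOX paralogs 1 to 5 lie highest, at 73.3% against 14.9%.

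Within the 4 HOX clusters with 10 kb on either side, nearly all BAF45D peaks were in the NSC libraries. ESC1 had 0 peaks and ESC2 had 1, within 1 kb of the end of HOXC13 (−log10 q 2.05), whereas NSC1 had 23 and NSC2 had 21. The HOXA window (chromosome 7, 27082993 to 27210091) had 8 and 5 peaks in NSC1 and NSC2, HOXB (chromosome 17, 48518526 to 48738750) had 6 and 8, HOXC (chromosome 12, 53928831 to 54066030) had 6 and 3, and HOXD (chromosome 2, 176077487 to 176200907) had 3 and 5. The strongest regions common to both NSC libraries lay in HOXA3 (27136487 to 27137096), in HOXC4 (54054234 to 54054685, 19.3 and 14.2) and in HOXB3, within 1 kb of an end of HOXB3 and of HOXB5 (48590128 to 48590387, 16.5 and 16.3). A region in HOXD8 (176130340 to 176130988) was the only one common to both in the HOXD window.

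Taken library by library, no cluster differed from random gene-end windows after adjustment. HOXA in NSC1 came closest, with 8 peaks against 2.12 (percentile 98.7, unadjusted p = 0.0376, adjusted p = 0.516), by a randomisation test over 10000 windows, which is not an exact test of the libraries. Summed over the 4 clusters, a count chosen after the data were seen, 12 NSC-only regions stood against 3.66 in random windows (ratio 3.28, p = 0.0048), again by random windows and not by an exact test of the libraries. The windows were matched on length but not on the number of gene ends within them. Peaks lay at gene ends more often than at random positions, so the dense packing of genes in the clusters was not accounted for. Windows of this length at random gene ends held 9.78 and 8.32 peaks on average in NSC1 and NSC2 over the 4 clusters, 1.72 in ESC1 and 5.65 in ESC2. At equal list length the NSC libraries had 3.5 peaks on average in the clusters and the ESC libraries 0.

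**Figure D4:**
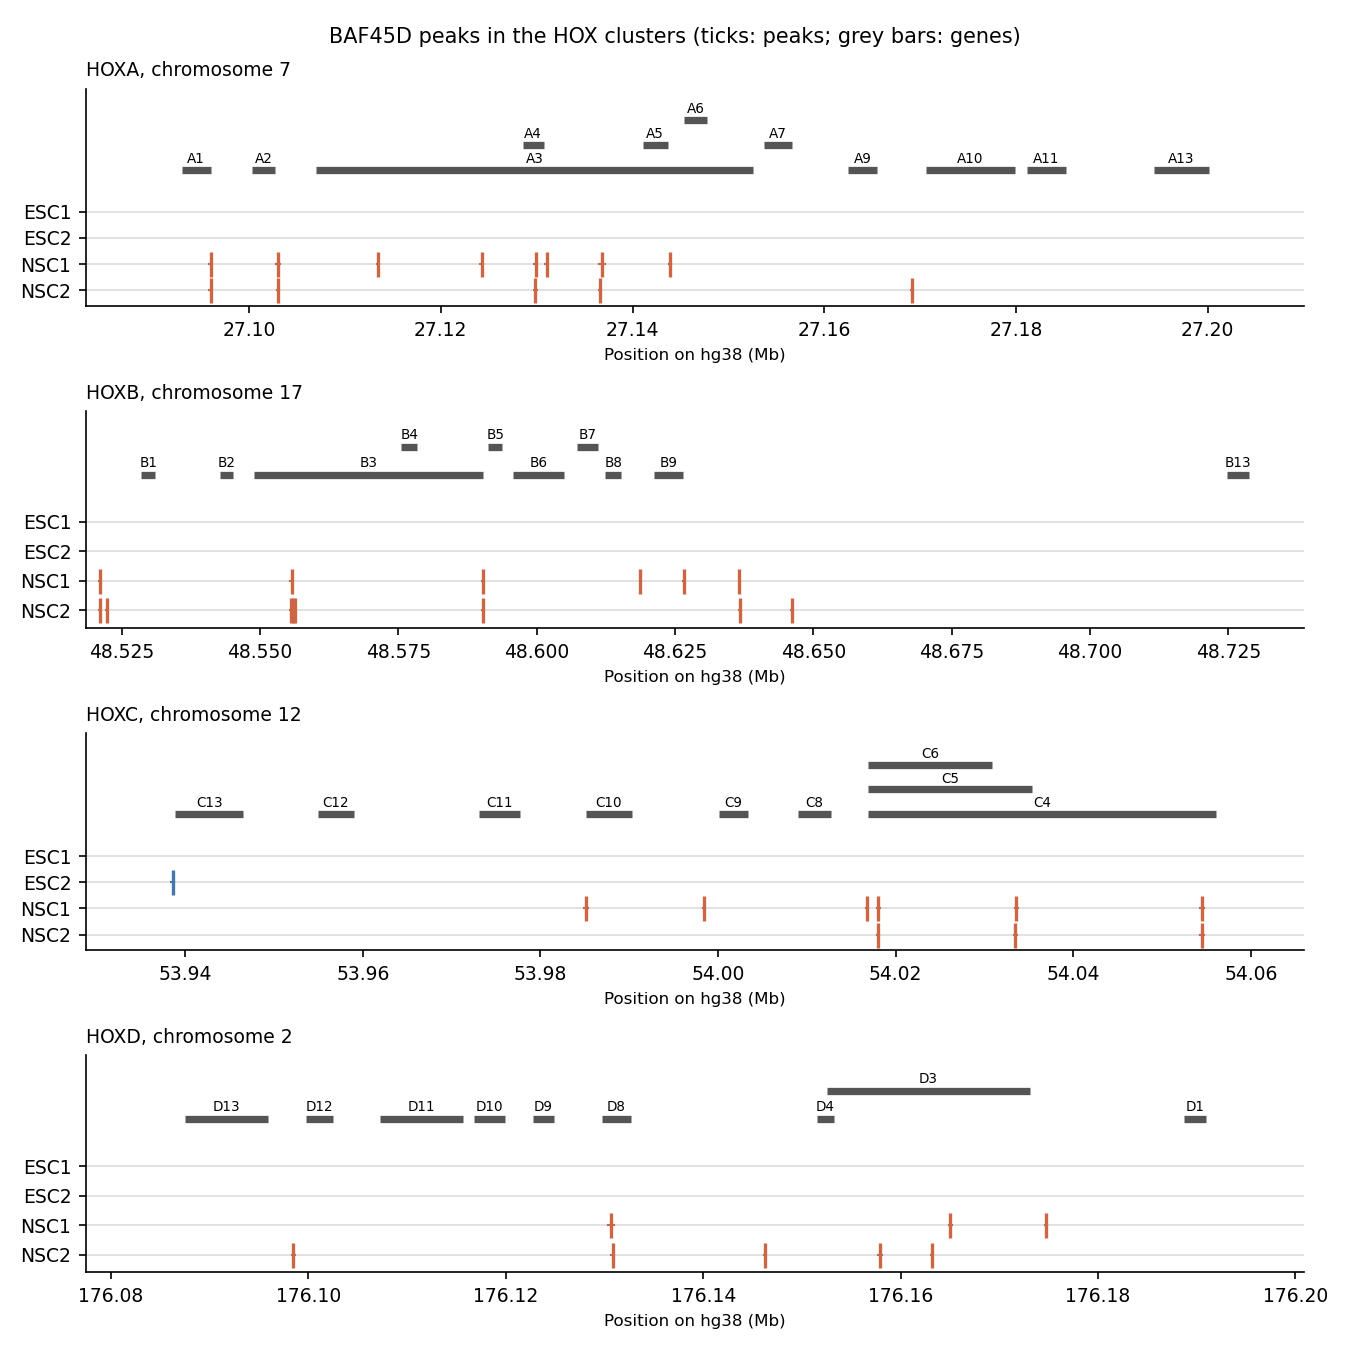
Peaks in the 4 HOX clusters with 10 kb on either side, by position on hg38 in Mb. Grey bars are HOX genes (labelled without the prefix) and vertical ticks are peaks of ESC1 and ESC2 (blue) and NSC1 and NSC2 (orange). ESC2 has 1 tick, next to HOXC13, and the NSC libraries have 23 and 21 over the clusters.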

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

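The peaks below lie on sequences outside the comparisons of cell types, and are given because they exceeded the 3 that a count of 0 would allow. On the mitochondrial genome, ESC1 and ESC2 had 6 peaks each, NSC1 had 11 and NSC2 had 10. On scaffolds not placed on a chromosome, ESC1 had 250 peaks, ESC2 had 248, NSC1 had 102 and NSC2 had 142. These scaffold peaks made up 5.52% and 1.93% of the ESC lists and 0.341% and 0.571% of the NSC lists. No explanation was tested for them.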

How the results depend on the processing

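Chosen after the data were seen were the counts without 1 library for peak numbers and HOX clusters, the distinct regions in place of genes, and the choice to follow WNT and HOX 1 to 5 genes. Overlap within ESC (46.2% to 82.8%) and within NSC (70.0% to 77.5%) stayed above the mean between cell types at each of the 4 settings run. Of the recomputed values for single lists and for numbers of genes taken by the naming rule, 121 stayed the same, 37 lost and 2 gained the call, 6 changed direction and 2 moved. For lists, the same means the same direction and side of the threshold, though not always size. Numbers of the naming rule were judged by a set factor. Among the other values, such as overlaps, gene-end shares and class sizes, 93 stayed within a set factor or their spread and 62 moved beyond it. HOX paralogs 1 to 5 by locus passed at all 9 settings (ratio 2.41 to 14.9, adjusted p 0.0011 to 0.042), each changed alone, as did olfactory receptors in the shared class at all 8 (adjusted p up to 0.000439). Apart from the count of distinct regions, these HOX settings counted neighbouring genes with shared regions as separate. The 6 changes of direction were WNT at gene ends at equal list length (odds ratio 0), protocadherins by locus at −log10 q of at least 5 (ratio 1.04), and without ESC2 the gene-end odds ratios of histone genes and protocadherins (1.71 and 1.92) and the locus ratios of histone and ZNF genes (2.15 and 1.00). Over the libraries left out, these ranged from 0.0621 to 1.71, 0.0646 to 1.92, 0.0874 to 2.15 and 0.737 to 1.00.

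At equal list length, where the peak ratio is fixed, overlaps were 46.2% (ESC), 70.0% (NSC) and 29.7% (between), gene-end shares 38.4% (ESC) and 42.0% (NSC), NSC-only and shared regions 1696 and 790, and NSC-only, ESC-only and shared genes 440, 251 and 739. Lists over-represented were 1 (NSC-only, Hippo and AP-1 genes, odds ratio 12.5, adjusted exact p = 0.00608) and 0 (shared), those under-represented 0 (NSC-only) and 0 (locus), and HOX peaks averaged 3.5 in NSC. At −log10 q of at least 5, overlaps were 82.8%, 77.5% and 55.8%, gene-end shares 41.8% and 33.6%, regions 7364 (NSC-only), 296 (ESC-only) and 766 (shared), ESC-only and shared genes 25 and 592, over-represented lists 1 (NSC-only) and 0 (shared), under-represented lists 1 (NSC-only) and 1 (locus), and HOX peaks 13.5. With all sequences, overlaps were 60.6% and 74.4% and 0 lists were over-represented in the shared class. With 50% overlap they were 57.4%, 71.3% and 36.8%. With 2.5 kb windows, gene-end shares were 33.8% and 31.4%, and over-represented lists numbered 1 (ESC-only) and 0 (shared). Without flanks, HOX peaks averaged 20.5 in NSC. The cause of these moves was not tested.

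Leaving out each library gave peak ratios of 2.17 (without ESC1) to 6.48 (without ESC2). Regions ranged from 13676 to 24945 (NSC-only), 856 to 7272 (ESC-only) and 1476 to 4113 (shared), and genes from 3244 to 5712, 62 to 473 and 1187 to 3656, since a class then asks for fewer libraries. Over-represented lists at gene ends ranged from 1 to 4 (NSC-only), 0 to 4 (ESC-only) and 0 to 3 (shared), under-represented lists from 3 to 7 (NSC-only) and 1 to 5 (shared), and by locus from 2 to 4. Paired by the labels' numbers, which name no shared batch, libraries gave peak ratios of 7.08 and 1.97, and 3.73 as their geometric mean with this replicate block, chosen after the data were seen; an exact test of 2 pairs cannot go below p = 0.5. For classes of peaks and tests across genes, no block could be fitted, since they have no fit over libraries. One start site per gene and the motif alternatives were not run, for want of strand and sequence. The low yield of ESC1 limits what can be called ESC-only or shared.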

Other observations

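Of the tests below, those of distinct regions per list, of dense tiles, of tag numbers, of tRNA list length, of nesting, and of gene lists at matched strength were chosen after the result was seen. Regions called in both NSC libraries and in no ESC library were dense at a few loci. The densest 100 kb tiles held 8 regions at ZNF608 (chromosome 5, 124600001 to 124700000), 7 at MAML2, which encodes a Notch coactivator (chromosome 11, 96000001 to 96100000), and 7 at TRIM2 (chromosome 4, 153200001 to 153300000), against a mean of 1.41 per tile with any. Counted as distinct regions per list, SOX genes had 33 against 8.68 in random lists matched on deciles of gene length (ratio 3.80, adjusted permutation p = 0.011). Lengths within a decile were left free, so very long genes may add to this and the following ratios. Neural progenitor genes had 41 against 15.8 (2.59, 0.022), Notch genes 38 against 17.8 (2.14, 0.011), FGF and EGF genes 41 against 21.7 (1.89, 0.022), retinoic acid genes 27 against 11.7 (2.31, 0.044), ribosomal protein genes 47 (2.13, 0.011) and liver and gut genes 0 against 6.85 (0.022). Left-out libraries ended the calls of FGF and EGF genes (without ESC2 1.64, adjusted permutation p = 0.0659, without NSC1 1.55, 0.132, without NSC2 1.45, 0.181), Notch genes (without NSC1 1.78, 0.0934) and retinoic acid genes (without ESC2 1.90, 0.0706, without NSC1 2.05, 0.0839), and the other 4 lists passed in all 4 such runs. In the planned count of genes by locus, none of these lists passed, with ratios of 1.33 for SOX (adjusted permutation p = 0.787), 1.63 for neural progenitor (0.325), 1.36 for Notch (0.713), 0.820 for FGF and EGF (0.809), 1.44 for retinoic acid (0.713), 1.49 for ribosomal protein (0.254) and 0 for liver and gut genes (0.114). A few genes carried some of these counts: the 2 members with most regions held 20 of the 33 in SOX genes, 24 of the 38 in Notch genes, 15 of the 27 in retinoic acid genes, 15 of the 41 in FGF and EGF genes and 12 of the 41 in neural progenitor genes, but 4 of the 47 in ribosomal protein genes. In SOX genes they were SOX5 and SOX6, which, named after their values were seen, held 20 and 16 peaks within 10 kb in NSC1, 17 and 12 in NSC2, 3 and 1 in ESC2 and 0 in ESC1.

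Transfer RNA genes were called at least as often in ESC as in NSC, although the ESC lists were shorter. Of 443 tRNA genes with 200 bp on either side, 161 and 255 were called in ESC1 and ESC2, and 152 and 150 in NSC1 and NSC2. Among lists of equal length 161 and 219 were called in ESC1 and ESC2, against 86 and 84 in NSC1 and NSC2. They took 3.52% and 1.82% of the ESC peaks and 0.416% and 0.523% of the NSC peaks. In both ESC and in no NSC library 54 were called, and the converse held for 10. The ESC-only tiles on chromosome 16 (3100001 to 3200000, 6 regions) and chromosome 6 (27500001 to 27600000, 5 regions) held 14 tRNA genes each. The densest ESC-only tile, on chromosome 20 (31000001 to 31100000, 7 regions), held 0. So did those on chromosome 4 (49100001 to 49200000, 6 regions) and chromosome 1 (143200001 to 143300000, 5 regions). Dense ESC-only tiles thus were not all at tRNA genes.

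For the tRNA genes called in ESC2, list length is argued against as the cause, since the ESC2 list held 0.508 times the peaks of the shorter NSC list. If reads shared between identical copies were the cause, multi-copy families were predicted to be more frequent among genes called in ESC2 and no NSC library. They were rarer there (42.5% of 106) than among those also called in NSC (63.9% of 147, odds ratio 0.416, 95% interval 0.241 to 0.716, Fisher's exact test, p = 0.000858). Shared reads in the NSC libraries would also move multi-copy genes into the second group, so this result does not decide whether reads were shared. A difference between the cell types was not tested and stays open. Untargeted transposition at open chromatin also stays open, since no control library was used here.

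Tag numbers argue against depth as the cause of the larger number of NSC peaks, since the NSC libraries had 0.276 times the tags of the ESC libraries. Weaker ESC enrichment of the same gene-end sites cannot be told apart from partly different sites, since of 1268 genes called in both ESC libraries, 95.1% (95% Wilson interval 93.8 to 96.2) were called in NSC1 and 93.6% (92.1 to 94.8) in NSC2, against 99.9% and 99.7% of equally many strongest genes of the other NSC library, a shortfall of 4.81 and 6.07 percentage points. Equally many strongest genes of ESC1 alone gave 92.6% and 91.2%, those of ESC2 alone 97.6% and 96.2%, and the 1016 gene-end regions of both ESC libraries 92.0% and 90.5%, so the shortfall did not pass 5 points beyond the intervals in each case, as the test required. The reference lies near 100% by choice, since it takes the strongest NSC genes, so a shortfall against it decides little. Of all 7602 genes called in NSC2, 90.8% were called in NSC1, against 95.1% of the ESC genes. Elsewhere, where most NSC peaks lay, 44.7% (42.1 to 47.3) and 47.2% (44.6 to 49.8) of 1426 regions of both ESC libraries were called in NSC1 and NSC2. The strongest NSC regions gave 99.1% and 99.8%, again near 100% by choice, and 70.1% of all 17112 NSC2 regions elsewhere were in NSC1. Many ESC regions there thus had no NSC peak. Background calls were not filtered or measured, so this does not decide whether weaker ESC enrichment of the same sites accounts for the difference. A difference in BAF45D binding between the cell types was not tested and stays open.

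With each region counted once and set against gene-end regions of the same NSC strength, 3 of the 33 lists differed in how often regions of both NSC libraries had an ESC peak. Neural progenitor genes had one less often (3 of 17 against 8.60, adjusted permutation p = 0.0242), and histone genes (17 of 22 against 9.95, 0.0242) and ZNF genes (109 of 190 against 83.9, 0.0066) more often. Without ESC2, 0 lists passed, with 2 of 17 against 2.99 (adjusted permutation p = 1), 3 of 22 against 2.61 (1) and 24 of 190 against 22.9 (1), and without NSC1 neural progenitor genes did not (4 of 18 against 8.34, 0.199), while TGF-beta, BMP and nodal genes did (4 of 25 against 10.5, 0.0286). Leaving out ESC2 thus ended all 3 calls and leaving out NSC1 ended 1. Without ESC2 only the short ESC1 list remained, where even TGF-beta, BMP and nodal genes at 0 of 18 against 2.45 did not pass. A shortfall such as that of neural progenitor genes could hardly pass in that run, so its loss decides little. Weaker enrichment of ESC alike at all gene-end sites cannot be told apart from differences between lists. A difference between the cell types was not tested and stays open. The requirement that a list pass without each library in turn was set after these values were seen, and without it the 3 lists would have counted against that explanation.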
